A study of Drosophila melanogaster with 3 samples.

How the data were processed

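The series measured where an eGFP-tagged Scute protein sat on chromatin in whole Drosophila melanogaster embryos. Per the labels, transgenic flies carried a C-terminal GFP fusion of sc, embryos of both sexes were collected at 0 to 14 h, chromatin was sonicated to 200 to 800 bp, and the immunoprecipitation used an antibody against GFP. The 3 biological replicates form a single group, so no comparison between groups was possible. The authors listed a control alignment among the inputs of the pooled list, per the text deposited with the samples; that control was not analysed here.

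The deposited region lists exist for the dm6 and dm3 assemblies. For each assembly the authors gave a list per replicate, a list from the replicates pooled together, and a thresholded set that passed the irreproducible discovery rate (IDR) procedure, per the text deposited with the samples. The value used to rank regions was the signal of each region as deposited, on a scale that belongs to its own list and is not normalized between libraries. The −log10 of the q-value was also deposited for each region, by the column layout of the format, and was used to count regions with a q-value under 5%. The offset of the summit from the start of each region came from the same deposited lists. The peak caller, the aligner and their versions are not given in the sources used here. Read depth is unknown, since the lists carry no read counts, so intervals cover only counting error over regions, windows or genes. In dm6 the pooled and replicate lists held 30000 regions each, and 3612 regions passed the IDR threshold. All 3612 were the highest-signal regions of the pooled list.

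Coordinates in dm6 were read against the Release 6 genome sequence and Ensembl release 115 gene models, on the arms 2L, 2R, 3L, 3R, 4 and X, and positions are 1-based. The dm3 lists served only as an alternative for counts, with no coordinate conversion. Analyses ran in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.

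The following tests, lists, windows and alternatives were fixed before the data were examined, except where stated. Replicates were compared by the share of the 3612 highest-signal regions of one list with a summit within 250 bp of a summit among the 3612 highest of another, against 100 random placements on the same arm. Regions of a replicate were matched to a thresholded region when that region was their nearest thresholded summit within 250 bp, and the highest signal was kept. This matching rule was chosen after seeing the data, because the rule used first let a weak region take the rank of a stronger neighbour. The rule used first took the highest region within 250 bp, and its values are given beside the results it changes. Unmatched regions took the lowest signal of the list.

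Summits were assigned to a promoter (within 500 bp of a start of a protein-coding gene), then to 5' UTR, CDS, 3' UTR, intron or intergenic sequence, and compared with 1000 random placements over called bases of the same arm. The density on X was set against that on 2L, 2R, 3L and 3R with an exact binomial test. Motifs were sought in windows of 100 bp on each side of a summit and in paired windows 1000 bp away, with an exact McNemar test. Pairs were dropped where both flanks lay within 300 bp of another summit, which removed 17 of them and kept 3595. The 21 motifs included the achaete-scute and Daughterless site GCAGSTG (S is C or G), 10 E-box hexamers, and 2 control heptamers without a known factor. Gene lists were tested by the number of genes with a summit in their territory, meaning the gene body plus 2 kb upstream, against 10000 random gene sets matched in 20 bins of territory length. A region counted for every gene whose territory held its summit, even where the start of another gene was nearer. The random sets drew genes singly and took no account of listed genes lying side by side. Tests were two-sided, shares carry 95% Wilson intervals, and Benjamini-Hochberg adjustment at 0.05 ran over the 6 features, the 21 motifs and the 17 lists separately.

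The lists covered proneural bHLH genes, sensory organ precursor genes, the Notch pathway with the E(spl) and Brd complexes, sex determination, neuroblast, neuron differentiation, glial, mesoderm and muscle, endoderm and gut, hemocyte and fat body, epidermis and cuticle, anterior-posterior patterning, dorsal-ventral patterning, Hox and cofactor, and cell cycle genes, all by name. Cytoplasmic ribosomal protein genes and chemoreceptor genes were taken by symbol. For 2 listed genes the annotation used another symbol, found through synonyms. Named genes were those at the 15 thresholded regions with the best mean rank over the 3 replicates, by territory or otherwise by nearest start. Up to 4 genes with the best mean rank were added from each list fixed by name, which leaves out the 2 lists taken by symbol, as were ac, sc, l(1)sc and ase whatever their values.

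Alternatives covered the matching distance, the number of top regions, a stricter set, the assembly, promoter and motif windows, backgrounds, gene assignment and the removal of each replicate. For replicate overlap, the share found and rank correlation, removal left out the list of that replicate. For all other results it kept only thresholded regions found among the highest 3612 of both remaining replicates. Those values therefore mix the removal with a filter. The tests were first tried on simulated regions. With nothing planted, 0 of 21 motifs, 0 of 17 lists, 0 of 6 features and 0 of 32896 8-mers passed. The simulated regions lay at random positions, so these runs did not cover summits that differ from their flanks in base composition. With sites planted in simulated windows for the AS-C/Da E-box comparison, the recovered share over 3612 windows was 16.5%, which includes sites already in the genome. The planted motif, list and 8-mer each passed. In the planted list every gene was given a region at its start. These runs therefore do not show that smaller effects would pass.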

Results

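Scute is a proneural bHLH transcription factor of the achaete-scute complex that acts as a heterodimer with Daughterless, and it is also an X-linked signal in sex determination. Its tagged form was mapped by ChIP-seq in embryos of 0 to 14 h, in 3 biological replicates of a single group. The authors' thresholded set held 3612 regions in dm6, with a median width of 430 bp. Read depth is unknown. Regions with a q-value under 5% numbered 4853, 6346 and 6435 in replicates 1, 2 and 3, and 6504 in the pooled list.

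The first question was how far the replicates shared their regions. The region at px, a wing vein gene, ranked 1, 2 and 1 in replicates 1, 2 and 3. That in ush, which encodes a GATA cofactor, ranked 4, 1 and 2. Both were picked by their mean rank over these replicates, so their like ranks are not evidence of sharing. Of the 3612 thresholded regions, 2409 were found among the highest regions of all 3 replicates, 796 of 2 replicates, 389 of 1 and 18 of none. Each replicate held 85.0% ± 1.35 (SD, n = 3) of the thresholded regions among its highest 3612. The highest regions of any pair of replicates overlapped by 76.4% ± 0.307 (SD over 3 pairs), against 1.35% for random placements, whose highest value was 1.73% (permutation p = 0.0198, the smallest that 100 placements can give). Spearman's rho of region signal between replicates was 0.717 ± 0.00286 (SD over 3 pairs) across regions, which are not independent replicates, and under the matching rule used first it was 0.765. The thresholded set was itself derived from these replicate lists, so its overlap with them is not independent evidence.

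The second question was which genes lay at the strongest regions. The region with the best mean rank lay on 2R at 22514088 to 22514497 (dm6), 213 bp from a start of px, with a pooled signal of 2359 as given by the authors. The second lay on 2L at 480894 to 481288, in an intron of ush (FBgn0003963) and 1367 bp from the start of cbt, which encodes a zinc finger factor. The third, on 2R at 13035155 to 13035520, was intergenic, and its nearest start was that of CG13323, 11919 bp away. Regions followed at the promoter of CG14100, with a summit between Ugalt, a nucleotide sugar transporter gene, and eIF2Bbeta, a translation factor gene, in an intron of CG11050, and 2911 bp from the start of hll. The region on 3L at 22878709 to 22879115 overlapped the 5' ends of Chro, which encodes a chromosomal protein, and Ssl1, which encodes a TFIIH subunit, and its summit lay 67 bp inside Chro. It ranked 8, 9 and 7 in the replicates. The region at ph-p lay on X at 2137148 to 2137563, with ranks 9, 6 and 10, and an intergenic region lay 4204 bp from the start of Psc, the nearest start but outside its territory. The remaining regions of the best 15 lay at HmgZ and HmgD, which encode HMG-box proteins, at Art3, mRpS10 and CG34316, in an intron of cno, at Tina-1, and at PNPase and Gprk2. Of these 15 regions, 14 were also among the best 15 under the matching rule used first.

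Thresholded summits lay at promoters more often than chance, and they were scarce in coding sequence. Promoters held 1364 of 3612 summits, 37.8% (95% interval 36.2 to 39.4), against 11.4% for random placements, a ratio of 3.30. Coding sequence held 10 summits, 0.277% against 13.9%, and 3' UTRs held 24, 0.664% against 4.53%. Intergenic sequence held 20.5% against 30.1%. For each of these 4 features the permutation p was 0.0020, the smallest that 1000 placements can give, and the adjusted p was 0.0030. Introns held 40.3% of summits against 39.3% (permutation p = 0.238), and 5' UTRs held 0.498% against 0.794% (permutation p = 0.0460, adjusted p = 0.0551), neither past the threshold. The median distance from a summit to the nearest start was 1203 bp.

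**Figure D1:**
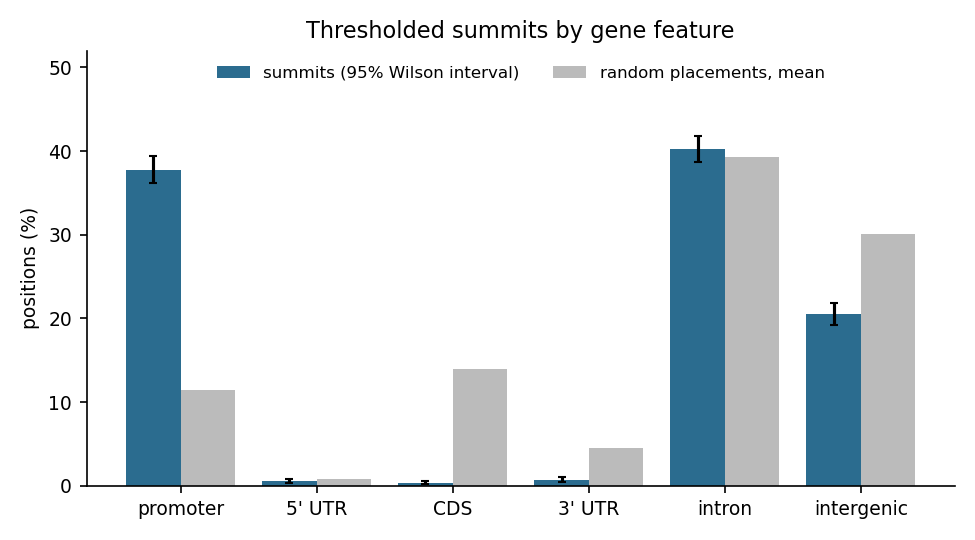
Share of the 3612 thresholded summits (blue bars, 95% Wilson interval) and mean share of random placements (grey bars) in each gene feature, in percent of positions. Promoters held 37.8% of summits against 11.4%, and coding sequence held 0.277% against 13.9%.

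The achaete-scute complex itself was examined because Scute is encoded there. No thresholded summit lay in the territories of ac, sc, l(1)sc or ase. Elsewhere in the complex 3 thresholded regions were found on X, at 362085 to 362514, 382795 to 383224 and 457734 to 458163, all in introns of CG32816. The first lay 7.73 kb upstream of ac and was among the highest regions of all 3 replicates, with ranks of 1825, 1434 and 1924. The start of another gene was nearer to it, at 5791 bp. The second lay 13.1 kb upstream of sc, with ranks of 2043, 2409 and 6146. Its nearest start was that of ac, 12979 bp away. The third lay 2798 bp upstream of ase (FBgn0000137), with ranks of 3291, 3693 and 2210. In the territory of sc (FBgn0004170) the best region of the pooled list ranked 7236, below the thresholded set.

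**Figure D2:**
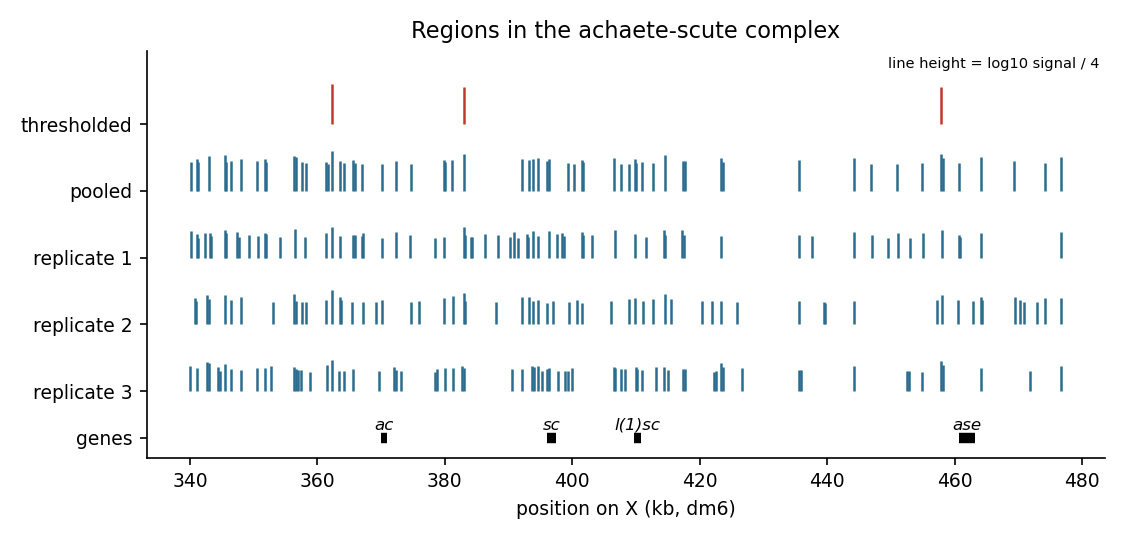
Map of the achaete-scute complex on X (position in kb, dm6) with the 4 genes as black bars and the summits of each region list as lines. Line height is the log10 of the signal within its own list, which cannot be compared between lists. None of the 3 thresholded regions overlaps the 4 genes.

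Because sc is X-linked and counts X chromosomes in sex determination, the density of regions on X was compared with that on the autosomes. The X chromosome carried 608 of the 3595 thresholded regions on the large arms, 25.9 per Mb. Among the autosomal arms 2L carried 30.7 per Mb and 2R 23.8 per Mb. The X to autosome ratio was 0.944 (95% interval 0.863 to 1.03; exact binomial p = 0.198), and the replicates gave 0.946 ± 0.0128 (SD, n = 3). The embryos were of both sexes, and the test made no allowance for the lower number of X copies in males. The direction depended on the background, since the ratio was 1.11 (exact binomial p = 0.0241) against all pooled regions. In the dm3 lists it was 0.887 (exact binomial p = 0.00588). There the arm length was the end of the last pooled region rather than the called bases, and the assembly also differed. The dm3 and dm6 ratios therefore cannot be compared directly.

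The next question was whether the textbook site of achaete-scute and Daughterless heterodimers stood at the summits. GCAGSTG was found in 4.65% of summit windows (95% interval 4.0 to 5.38) and in 7.23% of windows 1000 bp away (6.43 to 8.13), a ratio of 0.642 (exact McNemar p = 4.42e-06, adjusted p = 4.64e-05). Sites more frequent at summits were the E-box CATATG, 8.46% against 6.34% (exact test, adjusted p = 0.00159), and the GATA site, 7.96% against 6.12% (exact test, adjusted p = 0.00638). In all, 2 of 21 motifs were higher at summits, 10 were lower and 9 did not pass. The lower ones included both control heptamers, with GACGSTC at 0.640% against 1.67% (exact test, adjusted p = 0.000314). Mean GC content was 34.7% ± 6.90 (SD, n = 3595 windows) at summits and 42.1% ± 9.18 in the flanks.

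Against random windows matched on GC content the direction for GCAGSTG turned. It was found in 4.62% of summit windows and 3.54% of matched windows, a ratio of 1.30 that did not pass (exact McNemar p = 0.0237, adjusted p = 0.0996). The E-box CAGCTG was higher in this comparison, 7.86% against 4.43% (exact test, adjusted p = 1.78e-08), as were the GAGA repeat, 3.57% against 1.91% (exact test, adjusted p = 0.000187), CATATG and the GATA site. No motif was lower, and 17 of 21 did not pass. Among summits over 500 bp from a start the ratio against flanks was 0.754 and no longer passed (exact test, adjusted p = 0.0955). Against summits of the lowest-ranked pooled regions the GCAGSTG ratio was 0.702 (Fisher's exact test, adjusted p = 0.00175).

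**Figure D3:**
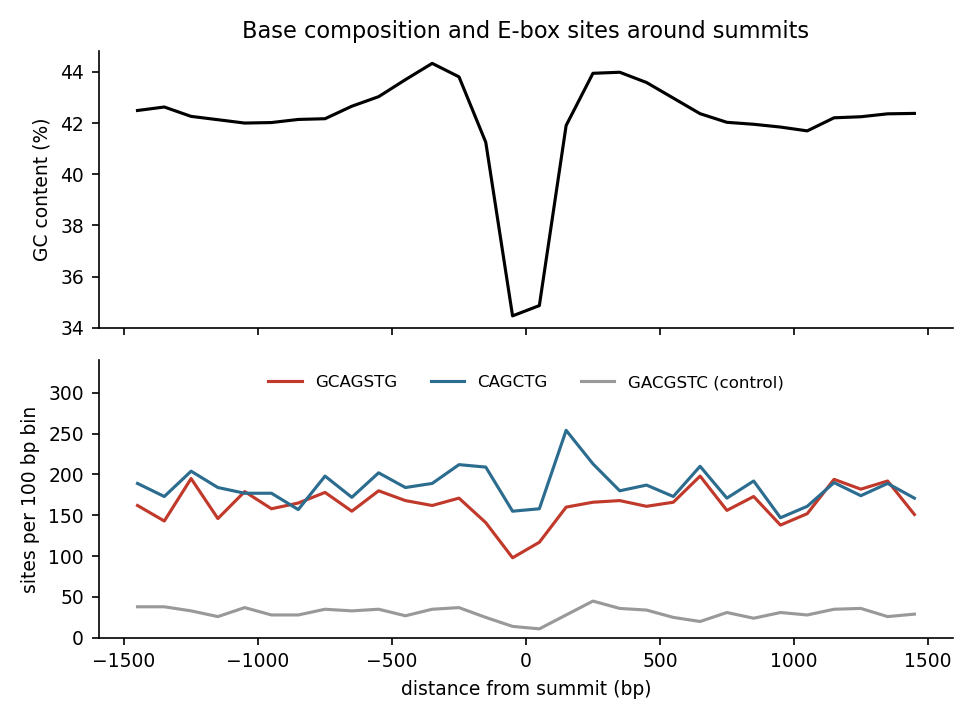
Mean GC content in percent (upper panel) and number of sites per 100 bp bin over the thresholded summits (lower panel) by distance from the summit in bp, for GCAGSTG, CAGCTG and the control heptamer GACGSTC. GC content falls at the summit, where GCAGSTG and the control are also fewer.

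Of 89 regions, namely the best 15 and the best region of each gene with one in the 15 lists fixed by name, 2 held a GCAGSTG site in the summit window. At cpo, a sensory organ precursor gene, the site CACCTGC lay on 3R at 17919147 to 17919153, upstream of the gene, within ACTAAAGCGACACCTGCCGGCGCGCCA. At E(spl)m8-HLH, a Notch target outside the rule for named genes and chosen after its values were seen, the site GCAGCTG lay in the promoter on 3R at 26040087 to 26040093 within CTACGAAGTTGCAGCTGTTCCTTGTGA.

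GCAGSTG was also compared between regions of high and low signal. The fifth of regions with the strongest mean rank, 723 regions, had the site in 3.46% of windows (95% interval 2.35 to 5.05). The fifth with the weakest, 722 regions, had it in 5.82% (4.33 to 7.77), a ratio of 0.594 (Fisher's exact p = 0.0340). The groups between them held 4.29%, 6.09% and 3.46% in order of falling signal, so the share followed no steady order. This call rested on the matching rule chosen after seeing the data, and under the rule used first the ratio was 0.881 (Fisher's exact p = 0.612). Ranking by the authors' signal gave 0.799 (Fisher's exact p = 0.371). Leaving out replicate 1, 2 or 3, with only regions found in both other replicates kept, gave 0.688, 0.599 and 0.576, none past the threshold.

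The last question was which gene groups carried regions. Cytoplasmic ribosomal protein genes did so most often, with 56 of 88 genes against 11.7 in random sets, a ratio of 4.79. RpS27 had a summit 5 bp from its start, RpL7 one 44 bp away and RpL28 one 52 bp away. Chemoreceptor genes, expressed mainly in sensory neurons, had regions at 4 of 179 genes against 29.1, a ratio of 0.138, and these were Or88a, Gr5a, Gr93a and Gr32a. In regions found in both other replicates the ratio was 0.134, 0.0445 and 0.0448 without replicates 1, 2 and 3. It was 0.437 with territories of 5 kb on both sides, and all of these passed the threshold. For ribosomal protein genes the ratio was 2.27 with 5 kb on both sides and 9.998 by gene body only, also past it. The examples from these 2 lists fall outside the rule for named genes and were chosen after their values were seen. For both lists the permutation p was 0.00020, the smallest that 10000 sets can give, and the adjusted p was 0.0017. The other 15 lists did not pass, with adjusted p from 0.126 to 1 in the same permutation test, and 1 of them had an unadjusted p under 0.05. In all, 2858 of 13945 protein-coding genes had a region.

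The list with an unadjusted p under 0.05 was the Notch pathway with the E(spl) and Brd complexes, which act in lateral inhibition, at 10 of 25 genes against 5.08 (ratio 1.97, permutation p = 0.0222, adjusted p = 0.126). Its regions included those at E(spl)m3-HLH, ranks 182, 113 and 94, gro, which encodes a corepressor, ranks 280, 259 and 199, E(spl)m7-HLH and E(spl)mdelta-HLH. Of the 10 genes, 7 lay in the E(spl) complex with summits within 45.9 kb on 3R, and the random sets did not account for this clustering. Without replicate 3, and with only regions found in both replicates 1 and 2 kept, this list passed, at a ratio of 2.41 (permutation test, adjusted p = 0.0249). It also passed in the 50% of regions with the highest authors' signal, at 3.09 (permutation test, adjusted p = 0.0034). In all it passed in 3 of 9 alternatives, and elsewhere the ratio was 1.45 (gene body only) to 2.32 with adjusted permutation p from 0.0635 to 0.863. Sensory organ precursor genes had regions at 10 of 18 genes against 6.78 (permutation test, adjusted p = 0.467), among them chn, ranks 65, 53 and 47, edl, numb, a cell fate determinant gene, and cpo. Assigned by nearest start, this list passed at a ratio of 2.39 (permutation test, adjusted p = 0.0068), as did the Notch list at 2.33 (permutation test, adjusted p = 0.0229). In the other 8 alternatives the sensory organ precursor list did not pass, with adjusted permutation p from 0.0669 to 0.573.

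Among the 11 proneural bHLH genes da alone had a region, against 1.92 in random sets. That region, on 2L at 10386316 to 10386745, lay 1574 bp from the start of da and 269 bp from that of Cdk1, a cell cycle gene, and the nearest start, of neither gene, was 131 bp away. In regions found in both other replicates, the ratio was 0 without replicate 2 or replicate 3. This region ranked 3964 in replicate 1, outside the highest regions of that replicate. The filter therefore removed it whenever replicate 1 was one of the replicates kept. Neuroblast genes had 4 of 23 against 7.44, at brat, grh, pros and insc. Neuron differentiation genes had 3 of 16 against 7.07, at elav, ChAT and fne, and elav ranked 123, 97 and 163. Sex determination genes had 5 of 14 against 3.77, including dsx, fru, gro and Sxl, where the summit lay 365 bp from a start. Glial genes had 6 of 12 against 3.74, including pnt, moody, Gs2 and loco.

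Mesoderm and muscle genes had regions at 8 of 18 against 6.85. Mef2, a muscle transcription factor gene, had ranks 53, 52 and 39, with stumps, Msp300 and sls below it. The Mef2 summit lay 1079 bp from a start of Mef2, and the nearest start, of another gene, was 141 bp away. Dorsal-ventral patterning genes had 8 of 18 against 6.15, with ush, brk, sim and sog. Endoderm and gut genes had 6 of 12 against 4.08, with otp, bowl, fkh and Poxn, although Poxn, placed in this list beforehand, is known as a sensory organ gene. Epidermis and cuticle genes had 7 of 13 against 5.34, with grh, yki, ovo and sdt. Hemocyte and fat body genes had 4 of 12 against 4.30, with ush, FASN1, lz and Pxn, a ratio of 0.931. In regions found in both other replicates, the ratio was 0.292, 0.568 and 0.288 without replicates 1, 2 and 3. The regions at lz and Pxn were each among the highest of only 1 replicate, so this filter removed them whichever replicate was left out. The Pxn summit lay 1480 bp from a start of Pxn and 171 bp from that of another gene. Hox genes and cofactors had 5 of 10 against 4.70, with Abd-B, Antp, hth and lab. Cell cycle genes had 5 of 15 against 3.81, with CycE, trbl, E2f2 and E2f1. The E2f2 summit lay 1986 bp from a start of E2f2 and 112 bp from that of another gene. Anterior-posterior patterning genes had 3 of 23 against 5.42, at oc, cad and hry, a ratio of 0.554. In regions found in both other replicates, the ratio was 0.238, 0.465 and 0.236 without replicates 1, 2 and 3.

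**Figure D4:**
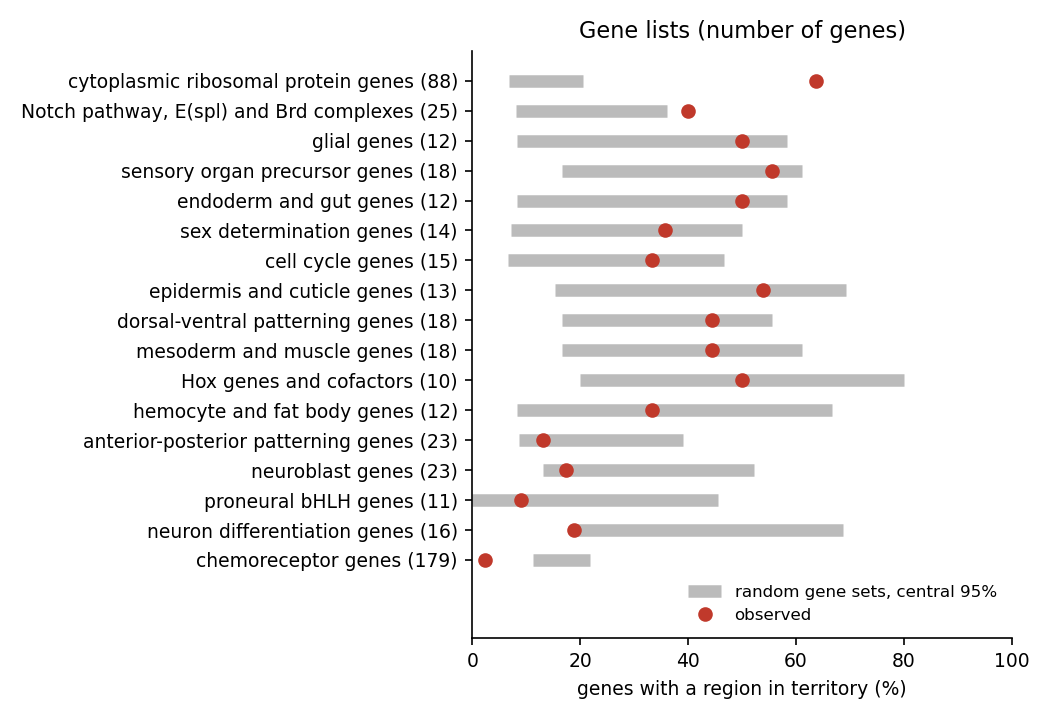
Percent of the genes of each list with a thresholded region in their territory (red points) and the central 95% of random gene sets matched on territory length (grey bars), with the number of genes in parentheses. Ribosomal protein genes, at 63.6%, and the Notch list, at 10 of 25 genes, lie above their ranges, and chemoreceptor genes, at 2.23%, lie below theirs. The Notch list did not pass after adjustment.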

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

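The comparison with windows matched on GC content was planned as an alternative, but its use as a test of base composition, like the test of summit placement, was chosen after the result was seen. The tests on ribosomal protein genes and divergent promoters were chosen before it. Each pattern below was found and examined in the same lists, and with a single group and no untagged sample analysed here, no biological explanation was tested.

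The pooled dm6 list held 2892 regions with a q-value under 5% below the IDR threshold, a signal outside the set the comparisons used. Of these, 365 (12.6%) also had a region under 5% in all 3 replicates, and 30.5% of the summits (95% interval 28.9 to 32.2) lay at promoters. GCAGSTG was found in 5.98% of their windows and 6.97% of flanks (exact McNemar p = 0.160). In the dm3 pooled list, 5 regions with a q-value under 5% lay on sequences outside the 6 arms.

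GCAGSTG was rarer at summits than 1000 bp away. For GCAGSTG taken as a whole, summits lying to one side of the sites is argued against. Sites per base at 100 to 300 bp were 0.959 times those at 700 to 1500 bp (95% interval 0.878 to 1.05). This does not extend to CAGCTG, the core of the GCAGCTG form of the site. CAGCTG had 209 to 254 sites per 100 bp bin at 100 to 300 bp and 147 to 204 at 700 to 1500 bp. That difference was not tested, and GCAGCTG and GCAGGTG were not counted apart. Base composition may account for the lower share of GCAGSTG, because against windows matched on GC content the ratio was 1.30. Against the lowest-ranked pooled regions, whose GC content was not compared, the share stayed lower, at a ratio of 0.702. Why the summits are poor in G and C stays open.

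Regions were frequent at ribosomal protein genes. Starts of neighbouring genes are argued against, since 96.4% of the 56 genes with a region had a summit within 500 bp of their own start (95% interval 87.9 to 99.0). Recovery of any strongly transcribed chromatin was examined at tRNA genes. These had a nearby summit 0.906 times as often as random placements (7 of 290 genes against a mean of 7.73, permutation p = 1). With so few summits and no interval on the ratio, that test cannot decide the question even for tRNA genes. It also says nothing about chromatin transcribed by RNA polymerase II, and repeated tRNA genes may be hard to map. Nonspecific recovery at active promoters therefore stays open beside recruitment of Scute, and an untagged sample would be needed to separate them.

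Many promoter summits lay near divergent pairs of starts. Of 1364 promoter summits, 34.3% had such a pair (95% interval 31.8 to 36.9), against a mean of 25.5% and a highest value of 28.4% in 100 draws around random starts (permutation p = 0.0198, the smallest these draws can give). More starts in reach is argued against as the whole account. The draws were not matched on gene activity, so a preference for active promoters may still contribute and was not tested.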

How the results depend on the processing

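The earlier matching rule was the only alternative chosen after seeing the data. Of 69 alternatives, 49 kept the direction and side of the threshold (or moved by less than 1 SD, or for a count of lists by at most 1.5 times), 9 lost the threshold, 1 gained it, 2 reversed and 8 moved. Replicate overlap and promoter share kept theirs under every alternative run. Outside the comparisons between replicates, leaving out a replicate also restricted the set to regions found in both others. The cause was not tested unless given.

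Against windows matched on GC content the E-box ratio at summits reversed to 1.30, and at summits over 500 bp from a start it was 0.754 and lost the threshold with fewer regions. The X ratio reversed to 1.11 against pooled regions and passed at 0.887 in dm3, where arm lengths were measured in another way. The E-box ratio by signal lost its threshold with the stricter set (0.558), with regions found in all 3 replicates (0.619), with a window of 250 bp (0.989), with the authors' ranking (0.799), with the earlier matching rule (0.881), and without each replicate (0.576 to 0.688). With 50 bp windows it passed, at 0.368.

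The share of thresholded regions found in each replicate was 80.3% at 100 bp, and, by construction, 51.2% with 50% of N and 97.7% with 2 times N. Leaving out a replicate gave 84.6% to 85.8%. Spearman's rho was 0.768 in the stricter set, 0.732 as Pearson's r of log2 signal, 0.714 to 0.720 without each replicate and 0.765 with the earlier matching rule. By nearest start, 4 lists passed instead of 2.

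Among lists that never passed, epidermis and cuticle genes turned to 0.961 in regions found in all 3 replicates, 0.903 without replicate 3 and 0.969 by gene body. Without replicates 1 and 2 their ratio stayed higher, at 1.36 and 1.34. Hemocyte and fat body genes turned to 1.37 with 5 kb on both sides, 1.79 by nearest start and 1.12 by starts within 1 kb, but were lower, at 0.310, in regions found in all 3 replicates. Anterior-posterior patterning genes turned to 1.33 by nearest start, and Hox genes to 0.681 and cell cycle genes to 0.901 by starts within 1 kb. Ribosomal protein and chemoreceptor genes passed in all 9 alternatives, at ratios of at least 2.27 and at most 0.437. The Notch list passed in 3 of 9 and sensory organ precursor genes in 1 of 9. Unknown read depth limits what can be said of regions below the threshold.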

Other observations

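All tests in this part were chosen after the results above were seen, and the values are descriptions with no explanation tested. Of 9 further gene lists set against random sets, 3 passed the threshold after adjustment over the 9 and 6 did not. Mitochondrial ribosomal protein genes had regions at 22 of 73 genes against 7.83 in random sets (ratio 2.81, permutation p = 0.00020, adjusted p = 0.00090). Cytochrome P450 genes had 3 of 85 against 15.2 (ratio 0.197, permutation test, adjusted p = 0.0012), and cuticle protein genes 1 of 111 against 13.8 (ratio 0.0725, adjusted p = 0.00090). Clustering of listed genes along a chromosome, which would make such p-values too small, was not accounted for. Proteasome genes had 3 of 48 against 6.48 (permutation test, adjusted p = 0.337), translation initiation factor genes 9 of 44 against 8.90 (permutation test, adjusted p = 1), insulator protein genes 2 of 10 against 2.15 (permutation test, adjusted p = 1) and chorion protein genes 0 of 9 against 1.15 (permutation test, adjusted p = 0.744). The cuticle, chorion and insulator lists were corrected after a first count had been seen, because the symbol rules took in unrelated genes and 1 gene appeared under 2 names.

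Genes of the Polycomb and Trithorax groups, which keep developmental genes off or on, had regions at 10 of 18 genes against 6.13 (ratio 1.63, permutation test, adjusted p = 0.195). Without ph-p, Psc and Trl, which had been seen first, the count was 7 of 15 against 4.88 (ratio 1.44, permutation test, adjusted p = 0.538). Trl, which encodes the GAGA factor, carried 5 regions, the best of them on 3L at 14759318 to 14759723 with ranks 16, 18 and 18. The best regions of E(z) and brm lay 58 bp and 138 bp from their own starts, while those of trx, osa and psq lay 3044 bp, 13944 bp and 2549 bp away.

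Short sequences were compared between windows of 300 bp on each side of the summits and paired windows 3000 bp away. Several searches with other window sizes, distances, word lengths and subsets of regions were run before this one, and their results are not adjusted for. Of 32896 8-mers, 1273 were higher at summits and 1837 lower after adjustment, over 3542 pairs, with mean GC content of 40.02% and 42.8%. CACTGAGA was found in 7.31% of summit windows and 1.67% of paired windows (ratio 4.39, exact McNemar adjusted p = 6.27e-29), and CACTGTGC in 9.06% and 2.34% (ratio 3.87, adjusted p = 2.36e-31). GCTATCGA was found in 3.05% and 0.791% (ratio 3.86, exact McNemar adjusted p = 2.89e-10), and AGAGAGCG in 8.36% and 2.37% (ratio 3.52, adjusted p = 6.03e-26). The 8-mer CACTGAGA occurred at 82.5 sites per 100 bp over all summits within 100 bp of them, and at 11.1 sites per 100 bp at 700 to 1500 bp.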
